A study of Mus musculus with 6 samples.

How the data were processed

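RNA was taken from 6 samples of mouse stem-like medulloblastoma cells, 2 for each of 3 CRISPR guides (sgGal4-4, sgMiat-6 and sgMiat-96). Per the labels' protocols, RNA was isolated with a column kit and 1 µg of total RNA per sample entered a library kit for mRNA. The labels do not say whether strand was kept, or whether the 2 replicates of a group were separate cultures. The p-values then measure the spread between these samples only, which may be technical.

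Reads were aligned with STAR to GRCm38 (mm10), per the submitters' processing notes. The version, the read counter and the annotation release are not given in the sources used here. Each deposited file lists a count, an FPKM and a TPM for every RefSeq transcript, per the file headers. The counts are whole numbers. The FPKM of a row was taken to be its count divided by the transcript's length and by the sum of the count column. That formula was assumed. What was checked is that count over FPKM kept a constant ratio to that of the first library, within 0.01%, in rows with an FPKM above 0. The deposited TPM values were not used, and FPKM served only to recover transcript lengths and zeros. The files hold 33984 rows for 24063 symbols, and 5261 symbols have more than 1 row. Isoform rows each count the reads they share, so rows cannot be added. The row with the highest total count over the 6 libraries was kept for each symbol. In sgMiat-96 replicate 2, 11223 rows with an FPKM of 0 are listed at 1 count, and no row is at 0. These were set to 0, which departs from testing the counts as deposited, and the listed values were tried as an alternative.

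Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, after filterByExpr by group and TMM scaling. A model of 3 groups was fitted to all 6 libraries, with 3 residual degrees of freedom, and quasi-likelihood tests gave p-values adjusted by Benjamini-Hochberg over 13220 genes. A gene was called at an adjusted p under 0.05. The contrasts were the mean of both Miat guides against sgGal4-4, each guide against sgGal4-4, and sgMiat-96 against sgMiat-6. The biological coefficient of variation was 0.099. Levels are CPM scaled by TMM, as mean ± SD over 2 libraries. The standard error of a log2 fold change is its absolute value divided by the square root of the test's F. It is approximate for genes near 0 counts. Fold changes were fitted with a prior count of 0.125. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3, the ratio of counts is given with a 95% interval (Clopper-Pearson). Floors and intervals cover counting error only.

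The libraries had between 18438891 and 19650274 counts in the rows kept, and 3 counts in a library correspond to between 0.149 and 0.173 CPM after TMM scaling. Replicates of a group differed by more than sampling noise, with a chi-square per gene of 4.13 for sgGal4-4, 19.1 for sgMiat-6 and 14.1 for sgMiat-96, where 1 is the value for sampling noise. Among symbols with at least 60 counts in all, 44 have the same counts as another symbol in every library, as Amd1 and Amd2 do, and genes with such copies, overlapping genes and antisense pairs are uncertain.

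Before the data were examined, 38 gene lists, the tests, the groups and the rule for named genes were fixed. Named were Miat, the 12 highest and 12 lowest log2 fold changes with both guides, the 3 highest and lowest per guide not yet named, and the 4 highest and lowest between guides. Candidates were called genes with a mean of at least 2 CPM and a symbol that is not a predicted gene, clone or pseudogene. For both guides, all Miat libraries also had to lie on one side of both controls. Of each called list up to 4 called members with the smallest adjusted p were named, and of each other list up to 2. The values of 1 gene that this rule named are not reported here. Lists with at least 5 tested members were tested with camera (correlation 0.01), and again with an estimated correlation and with fry. Genes at a lower bound occur in 7 lists, and putting them at their bound moved 0 of the list medians.

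Coordinates come from GENCODE M21 on GRCm38, in which 23843 symbols were matched, 23491 by transcript accession and 352 by symbol. Chromosome medians used genes with a mean of at least 5 CPM. The trend over transcript length or GC content was removed with a loess offset per library (span 0.3), and 98.5% of tested genes had a GC value. The tests were tried on simulated data with 12855 genes and known changes for both guides against sgGal4-4. edgeR recovered 71.2% of genes changed 1.5-fold, 83.1% of those changed 2-fold and 98.4% of those changed 4-fold, and 7 of 171 calls were false. The changed genes numbered 66, 65 and 64. In the data 66.5% of tested genes were called in that comparison, so the simulation does not test a contrast in which most genes move. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.

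The alternatives fixed in advance were DESeq2 size factors, total counts, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of 2 CPM, a replicate block, fits of the compared groups only, each library left out in turn, a 2-fold threshold and an adjusted p under 0.01. Added after seeing the data were the zeros as listed, summed isoform rows, every transcript row, leaving out Rn45s, removal of the length or GC trend, and leaving out the genes of chromosomes 1 and 15.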

Results

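Stem-like medulloblastoma cells were profiled by RNA-seq. Medulloblastoma is a tumour of the cerebellum, and the genotype given in the labels, Math1-Cre; SmoM2, switches on an active form of Smoothened, the signal transducer of the Hedgehog pathway, in granule neuron progenitors. The cells carried a CRISPR guide named for Gal4, a yeast protein (sgGal4-4, labelled wild type), or 1 of 2 guides named for the long noncoding RNA Miat (sgMiat-6 and sgMiat-96). Each of the 3 groups had 2 libraries, 6 in all. The deposited count columns summed to between 27324587 and 29671461 per library over all transcript rows. With 1 transcript row kept per gene symbol, they summed to between 18438891 and 19650274, and between 15200 and 15615 symbols had at least 1 count. Libraries of the same group had Spearman correlations across genes of 0.992 to 0.998. The correlations lay between 0.960 and 0.988 for the 2 Miat guides and between 0.884 and 0.936 for control against Miat libraries.

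The series title names depletion of Miat as the subject, so Miat was examined first in every library. The transcript (NR_003718, a lincRNA) lies on chromosome 5 from 112213228 to 112229395 on the minus strand of GRCm38. It had 140 and 139 counts in the sgGal4-4 libraries and 0 counts in each of the 4 Miat libraries. The control level was 7.13 ± 0.12 CPM (SD, n = 2), where CPM is the count scaled to library size with TMM factors. Against a floor of 3 counts over the group, Miat was at least 94.4-fold lower with sgMiat-6 and at least 83.4-fold lower with sgMiat-96. The adjusted p was 4.88e-07 and 4.05e-07 in edgeR's quasi-likelihood test. The other row listed for Miat (NR_033657) held the same counts in all 6 libraries.

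The main comparison asked which genes differed between the libraries of both Miat guides and those of the control guide. Of the fixed lists, 24 of 27 amino acid response genes, 13 of 18 astrocyte markers and 17 of 23 immediate early genes fell. Rises were seen in 23 of 32 p53 targets, 22 of 30 lysosomal genes, 16 of 28 glycolytic genes, 47 of 49 ribosomal protein genes and 28 of 32 respiratory chain genes. None of these lists was called with an estimated correlation (adjusted p = 0.183 to adjusted p = 0.607 with an estimated correlation), and the respiratory chain list was not called with the trend over transcript length removed (adjusted p = 0.0843). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 116 ± 2.41 CPM in the control to 489 ± 25.5 with sgMiat-6 and 641 ± 29.4 with sgMiat-96 (SD, n = 2 each). Trib3, a pseudokinase induced by Atf4, fell from 75.6 ± 3.30 to 8.34 ± 1.06 and 9.24 ± 1.40 CPM. Apoe, an apolipoprotein made by astrocytes, fell from 814 ± 51.8 to 19.3 ± 5.13 and 98.2 ± 13.1 CPM.

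**Figure D1:**
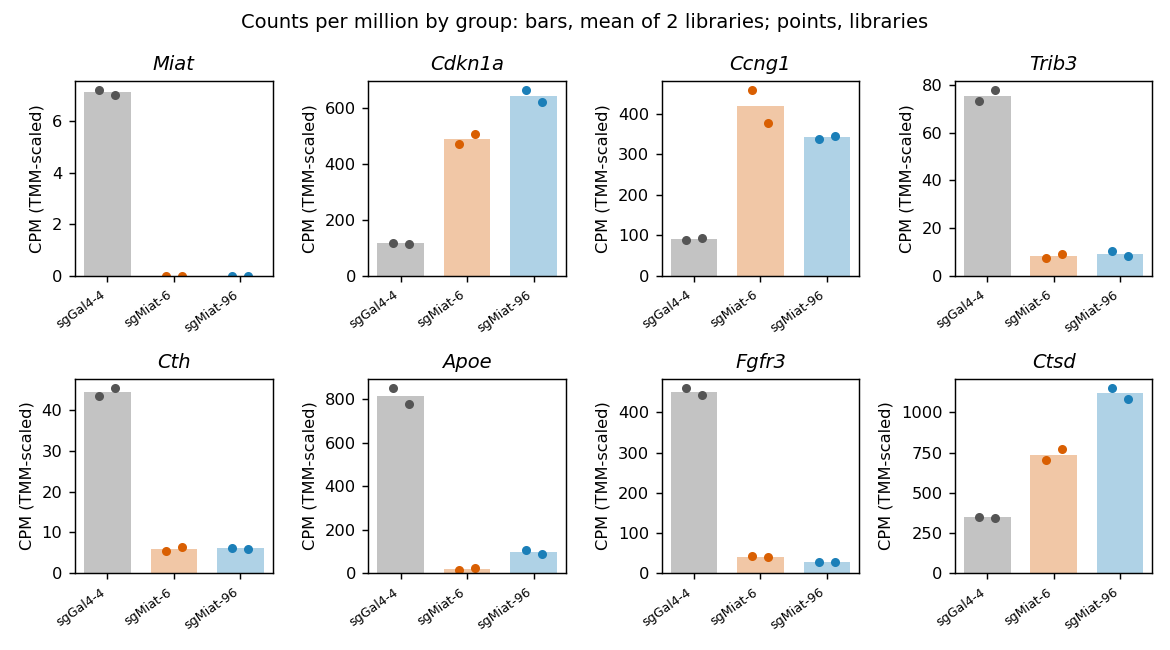
CPM (TMM-scaled, linear axes from 0) of 8 genes in the 3 groups; bars are means of 2 libraries and points are libraries. Miat was at 0 in the 4 Miat libraries, Cdkn1a, Ccng1 and Ctsd lay above the control libraries, and Trib3, Cth, Apoe and Fgfr3 lay below them.

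Of 13220 genes tested, 8794 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4379 higher and 4415 lower with the Miat guides. At least a 2-fold change was seen in 3318 of them, 1503 higher and 1815 lower. Scaled by total counts alone, the calls split into 3583 higher and 5196 lower, with the median of all genes at -0.13 on the log2 scale, and fold changes here are relative to TMM, under which that median was 0.00.

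Several genes were off in the control libraries and on in every Miat library. Map1lc3a, which encodes an LC3 protein of the autophagosome, had 0 counts in both control libraries, and reached 44.6 ± 7.74 CPM with sgMiat-6 and 73.5 ± 5.40 CPM with sgMiat-96 (SD, n = 2 each). It lies on chromosome 2 from 155276297 to 155278073 and was at least 759-fold higher. Ddt, the D-dopachrome tautomerase gene (chromosome 10, 75771230 to 75773414), was at least 543-fold higher. The AMPA receptor subunit gene Gria3 was at least 347-fold higher, with 38.7 ± 7.57 CPM under sgMiat-6 and 12.8 ± 1.12 CPM under sgMiat-96. She, AU022751, Dtd1, Pcsk1n, Hebp1, Ptprd, Col5a2 and Dhrs4 also had 0 control counts. Their lower bounds on the fold ran from 205-fold for Dhrs4 to 315-fold for She. Slc38a1, a glutamine transporter gene, had 1 control count against 6319 in the Miat libraries, a ratio of 3304 with a 95% counting interval of 593 to 130500.

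The opposite pattern was led by Wisp1, a matricellular protein gene on chromosome 15 from 66891320 to 66923201. It fell from 32.6 ± 2.33 CPM (SD, n = 2) to 0 counts in all 4 Miat libraries, at least 812-fold. Xlr3b on the X chromosome was at least 657-fold lower. The ephrin gene Efna1 was at least 323-fold lower, and Otx2, a homeobox transcription factor gene on chromosome 14 from 48657677 to 48673819, at least 312-fold lower. The potassium channel gene Kcnc4 and the transporter gene Slc22a29 were at least 189-fold and 147-fold lower. Hist3h2ba, Col22a1 and Lrrc7 kept 2, 1 and 1 counts in the 4 Miat libraries, against 883, 575 and 444 in the controls. Rfx4 fell from 55.0 ± 2.38 CPM to 5 counts in all, and Ctsc, which encodes the lysosomal protease cathepsin C, from 212 ± 6.13 CPM to 33 counts in all.

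Such switched genes were counted with a rule chosen after the values were seen, at most 3 counts together on one side and at least 5 CPM in every library on the other. By this rule 55 genes on 16 chromosomes were silent in the control and on in all Miat libraries, and 14 genes, Miat included, were silent in the Miat libraries and on in both controls. Taken by guide, 64 genes with sgMiat-6 and 62 with sgMiat-96 were on and silent in the control, and 26 and 19 were silent and on in the control. Between the 2 Miat guides the rule found 0 genes in either direction, while edgeR called 4850 genes between them.

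Of the 38 gene lists fixed before the data were examined, 35 had enough members to test and 11 were called by camera with a preset correlation of 0.01. Camera with an estimated correlation takes its p-values from the 3 residual degrees of freedom, which raises them when libraries are few. In that setting 0 of the 11 were called, and 4 lists had an unadjusted p under 0.05. The main adjusted p of each of the 11 called lists is therefore followed by the value from that setting. Where a range over 16 settings is given, it covers camera with the preset correlation only, under other scaling, blocking, left-out libraries, trend removal and each guide alone. Counts of genes adjusted over the list alone were the same as those over all genes for these 11 lists. The 27 measured amino acid response genes driven by Atf4 had the smallest p of the tested lists: 24 fell and 0 rose, with a median of -1.09 on the log2 scale (camera adjusted p = 8.74e-12, and adjusted p = 0.183 with an estimated correlation). Trib3 fell by 3.11 ± 0.12 (SE) on the log2 scale. Aldh1l2, a mitochondrial folate enzyme gene, fell by 3.02 ± 0.12, Cth, which makes cystathionine gamma-lyase, by 2.88 ± 0.12, and Pck2 by 1.88 ± 0.08.

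Of 32 measured p53 targets, 23 rose and 4 fell, with a median of 0.72 (camera adjusted p = 2.73e-06, and adjusted p = 0.183 with an estimated correlation). Cdkn1a rose by 2.27 ± 0.10 on the log2 scale, Ak1 by 2.13 ± 0.11 and Ccng1, the cyclin G1 gene, by 2.05 ± 0.11. Dcxr, also on this list, was at least 172-fold higher and had 0 control counts. Of 30 lysosome and autophagy genes, 22 rose and 4 fell, with a median of 0.64 (adjusted p = 2.91e-05, and adjusted p = 0.405 with an estimated correlation). Besides Map1lc3a, the sialidase gene Neu1 rose by 2.02 ± 0.12, the lysosomal channel gene Mcoln1 by 1.58 ± 0.12 and Ctsd, which encodes cathepsin D, by 1.39 ± 0.09. Of 28 glycolysis and hypoxia genes, 16 rose and 6 fell, with a median of 0.70 (adjusted p = 0.0061, and adjusted p = 0.405 with an estimated correlation). The glucose transporter gene Slc2a1 rose by 2.01 ± 0.12, and Bnip3 by 1.74 ± 0.11. Ldha, which encodes lactate dehydrogenase A, went from 716 ± 8.89 CPM to 1674 ± 108 and 2462 ± 174 CPM (SD, n = 2 each). Vegfa fell by 1.36 ± 0.08. Taken with sgMiat-6 alone, the glycolysis and hypoxia list had an adjusted p of 0.0775, the highest of 16 settings with the preset correlation, which began at 0.000482.

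Cytosolic ribosomal protein genes rose in 47 of 49 cases and fell in 0, with a median of 0.82 (adjusted p = 1.52e-09, and adjusted p = 0.607 with an estimated correlation). Their transcripts are short, with a median of 703 bp against 2843 bp for all tested genes, and with the trend over transcript length removed the median was 0.26 (adjusted p = 0.00244). Rps14 went from 684 ± 40.8 CPM to 1738 ± 184 with sgMiat-6 and 3189 ± 543 with sgMiat-96 (SD, n = 2 each). Rplp1, Rps7 and Rpl27 rose by 1.52 ± 0.12, 1.30 ± 0.12 and 1.25 ± 0.11 on the log2 scale. Ribosomal protein genes have many processed pseudogenes, so reads shared with such copies leave these levels uncertain. Of 32 nuclear genes of oxidative phosphorylation, 28 rose and 2 fell, with a median of 0.76 (adjusted p = 2.64e-05, and adjusted p = 0.607 with an estimated correlation). Ndufb8 and Ndufa1 of complex I rose by 1.86 ± 0.13 and 1.59 ± 0.14, Uqcrh by 1.15 ± 0.11 and the cytochrome c gene Cycs by 0.98 ± 0.10. These transcripts had a median length of 746 bp. With the length trend removed their median was 0.26 and the list was no longer called (adjusted p = 0.0843, the highest of 16 settings with the preset correlation, which began at 6.8e-07).

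Of 14 granule neuron progenitor genes, 10 rose and 2 fell, with a median of 1.21 (adjusted p = 0.036, and adjusted p = 0.565 with an estimated correlation). The cerebellar transcription factor genes Zic2 and Zic1 rose by 1.32 ± 0.11 and 1.09 ± 0.11. The adhesion gene Cntn1 had 3 control counts against 1014, a ratio of 177 with a 95% counting interval of 60.3 to 858. Meis2 fell by 1.78 ± 0.17. The call was lost without sgMiat-6 replicate 1 (adjusted p = 0.0722), with sgMiat-96 alone (adjusted p = 0.0888) and without the genes of chromosomes 1 and 15 (adjusted p = 0.166), against 0.00658 in the lowest of the settings with the preset correlation.

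Astrocyte markers fell in 13 of 18 cases and rose in 3, with a median of -1.07 (adjusted p = 0.000223, and adjusted p = 0.405 with an estimated correlation). Apoe fell by 4.22 ± 0.13 on the log2 scale, the growth factor receptor gene Fgfr3 by 3.71 ± 0.09 and Acsl6 by 3.21 ± 0.20, while S100b rose by 1.66 ± 0.13. Immediate early genes fell in 17 of 23 cases and rose in 4, with a median of -0.94 (adjusted p = 0.00331, and adjusted p = 0.338 with an estimated correlation). Egr1, a transcription factor gene, went from 354 ± 2.98 CPM to 85.1 ± 1.18 CPM with sgMiat-6 (SD, n = 2 each), and fell by 1.97 on the log2 scale with both guides. Arc and Atf3 fell by 6.12 ± 0.46 and 1.78 ± 0.16, and Jund rose by 1.18 ± 0.10. These genes respond within minutes to handling of cells. Notch pathway genes fell in 15 of 23 cases and rose in 5, with a median of -0.55 (adjusted p = 0.0054, and adjusted p = 0.338 with an estimated correlation). The glycosyltransferase gene Mfng fell by 5.26 ± 0.19, the receptor gene Notch3 by 2.80 ± 0.13, the ligand gene Jag1 by 2.53 ± 0.13 and Dner by 1.75 ± 0.09. With the length trend removed the Notch median was -0.24 (adjusted p = 0.00553). Without the genes of chromosomes 1 and 15 the Notch list had an adjusted p of 0.0747, the highest of 16 settings with the preset correlation, which began at 0.000532.

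Extracellular matrix and adhesion genes moved both ways, 16 up and 18 down of 37, with a median of -0.62 and a mean of -0.01 (adjusted p = 0.00443, and adjusted p = 0.607 with an estimated correlation). The proteoglycan gene Vcan fell by 8.76 ± 0.13 on the log2 scale, from 336 ± 23.9 CPM to below 1 CPM with either guide. The integrin gene Itga6 fell by 4.98 ± 0.13 and the laminin gene Lamc1 by 1.90 ± 0.10, while the collagen gene Col5a2 was at least 235-fold higher. The list's median was -0.10 with sgMiat-6 alone and -0.50 with sgMiat-96 alone. These transcripts are long, with a median of 5564 bp. The list was not called with the length trend removed (median -0.10, adjusted p = 0.0842) or without sgGal4-4 replicate 1 (adjusted p = 0.0718), against 0.000412 in the lowest of the settings with the preset correlation.

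**Figure D2:**
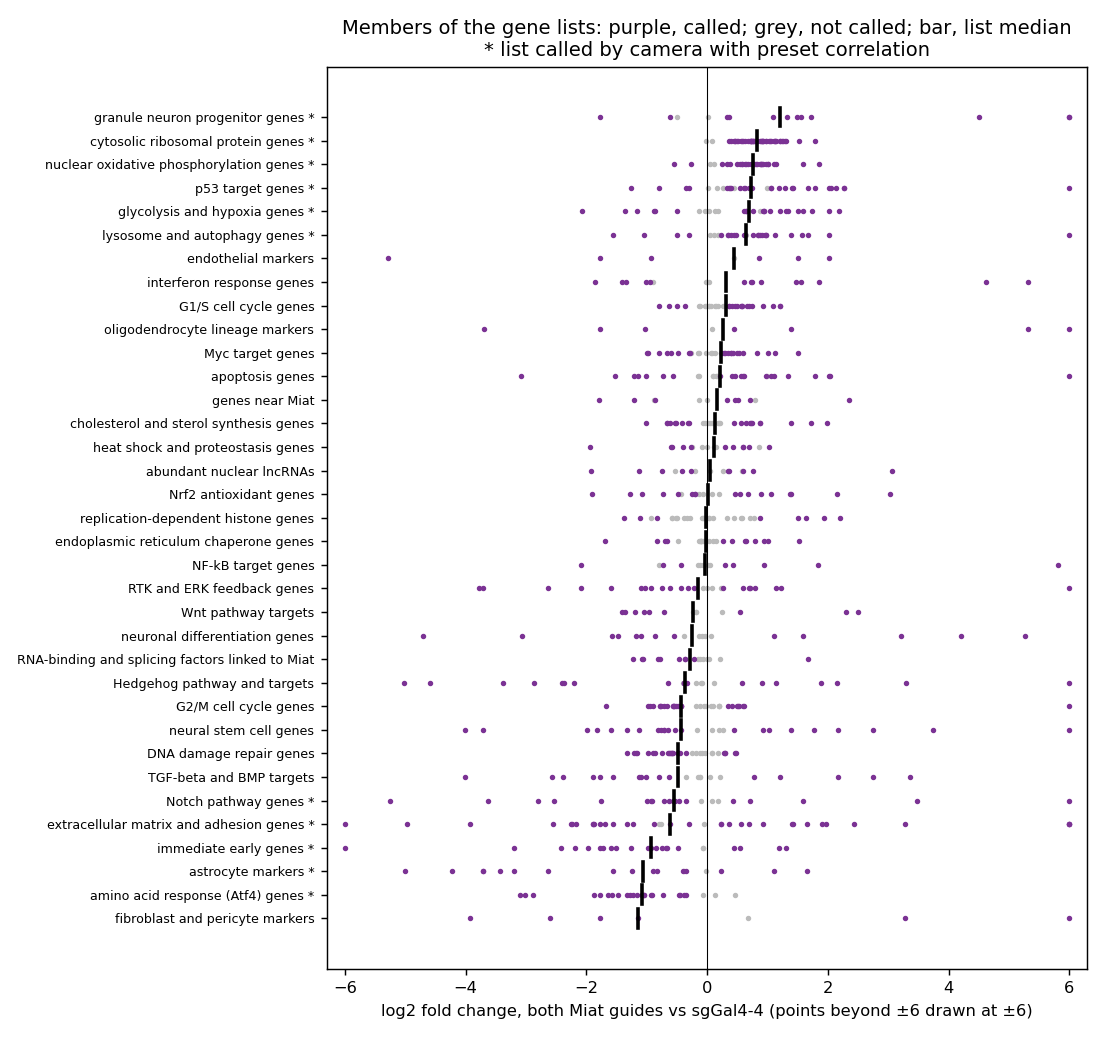
Log2 fold change of both Miat guides against sgGal4-4 for each measured member of the 35 tested lists; purple points were called, grey points were not, black bars are list medians and points beyond 6 are drawn at the edge. The amino acid response list shows 24 of 27 members lower and the ribosomal protein list 47 of 49 higher.

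The remaining lists were not called by camera in the model as designed, nor with an estimated correlation, and many held members that moved far in both directions. Of 24 Hedgehog pathway genes and targets, 7 rose and 12 fell, with a median of -0.36 (adjusted p = 0.253), or -0.05 with the length trend removed. The ciliary gene Evc fell by 4.59 ± 0.20 and the coreceptor gene Cdon rose by 3.29 ± 0.15. The direct targets Gli1, Ptch1 and Hhip, chosen after their values were seen, fell too: Gli1 fell by 2.88 ± 0.19, Ptch1 fell by 2.38 ± 0.20 and Hhip fell by 5.03 ± 0.29. Other members, also chosen after their values were seen, rose: Ccnd1 by 1.14 ± 0.09, Foxf2 by 1.88 ± 0.20, Foxf1 by 0.91 ± 0.14 and Igf2 by 2.15 ± 0.59. Sfrp1 had 0 control counts and lay between 0.45 and 0.92 CPM in the Miat libraries. Neural stem cell genes numbered 9 up and 14 down of 27 (median -0.44, mean 0.07, adjusted p = 0.106, or 0.047 with the GC trend removed), and Id1 fell by 4.01 ± 0.12. The median of that list was -0.05 with the length trend removed. Neuronal differentiation genes numbered 5 up and 8 down of 18 (median -0.26, mean 0.02, adjusted p = 0.494). Stmn3 rose by 3.21 ± 0.13 and Ncam1 fell by 1.18 ± 0.08. G1/S genes numbered 15 up and 4 down of 30 (median 0.31, adjusted p = 0.0855, or 0.0336 with the GC trend removed), with Gins2 and Ccne2 both up by 1.21 on the log2 scale (SE 0.11 and 0.12). G2/M genes numbered 8 up and 18 down of 35 (median -0.43, adjusted p = 0.42). The mitotic cyclin gene Ccnb2 rose by 6.18 ± 0.21, from 0.460 ± 0.0777 CPM in the control, and Cenpf fell by 1.67 ± 0.10. Myc targets numbered 14 up and 8 down of 31 (median 0.23, adjusted p = 0.494), and 9 down when adjusted over the list alone. Ddx18 fell by 0.98 ± 0.09. DNA damage repair genes numbered 5 up and 20 down of 33 (median -0.48, adjusted p = 0.071), with Prkdc and Xrcc6 down by 1.33 ± 0.13 and 1.16 ± 0.10. Without sgGal4-4 replicate 1 that list was called, as it was with sgMiat-96 alone (adjusted p = 0.0183). With an estimated correlation its camera adjusted p was 0.512 with sgMiat-96 alone and 0.607 with both guides. With the length trend removed its median was -0.10, and its adjusted p of 0.442 was the highest of the 16 settings with the preset correlation.

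Among lists of signalling and stress, Wnt targets had 3 members up and 6 down of 13 (median -0.23, adjusted p = 0.329). Lgr5 rose by 2.51 ± 0.16, and the oncogene Myc, on chromosome 15, went from 198 ± 1.90 CPM to 84.2 ± 0.936 and 88.4 ± 2.46 CPM (SD, n = 2 each). TGF-beta and BMP targets had 5 up and 11 down of 22 (median -0.49, adjusted p = 0.135), and Id2 rose by 2.17 ± 0.11. RTK and ERK feedback genes had 8 up, or 9 adjusted over the list alone, and 13 down of 26 (median -0.14, adjusted p = 0.106, or 0.047 with the GC trend removed). With the length trend removed their median was 0.025. The ephrin receptor gene Epha4 fell by 3.78 ± 0.15. Interferon response genes had 9 up and 5 down of 18 (median 0.32, adjusted p = 0.205), with H2-K1 and Usp18 up by 5.32 ± 0.35 and 4.63 ± 0.21. NF-kB targets had 5 up and 3 down of 14 (median -0.03, mean 0.36, adjusted p = 0.478). Ier3 rose by 5.81 ± 0.22 and Nfkb2 fell by 0.73 ± 0.11. Apoptosis genes had 14 up and 7 down of 29 (median 0.22, adjusted p = 0.157). Casp12 had 2 control counts against 1035, a ratio of 271 with a 95% counting interval of 74.7 to 2237, and Hrk fell by 3.08 ± 0.18. Nrf2 antioxidant genes had 9 up and 8 down of 22 (median 0.01, adjusted p = 0.494), with Nqo1 up by 2.15 ± 0.15 and Abcc4 down by 1.91 ± 0.11. Heat shock genes had 6 up and 5 down of 17 (median 0.12, adjusted p = 0.975). Hspa4l fell by 1.95 ± 0.10 and Cryab rose by 1.02 ± 0.11. Endoplasmic reticulum chaperone genes had 8 up, or 7 adjusted over the list alone, and 4 down of 22 (median -0.02, mean 0.07, adjusted p = 0.634), with Sdf2l1 up by 1.53 ± 0.14 and Ero1l down by 1.69 ± 0.11. Cholesterol synthesis genes had 11 up, or 12 adjusted over the list alone, and 9 down of 28 (median 0.13, adjusted p = 0.253), and Scd1 and Mvk rose by 1.98 ± 0.11 and 1.72 ± 0.12. Replication-dependent histone genes had 5 up and 3 down of 28 (median -0.02, mean 0.15, adjusted p = 0.779). Hist1h2ag rose by 1.64 ± 0.24 and Hist1h2bc fell by 1.12 ± 0.12. Scaled by total counts, the medians of the cholesterol, heat shock, Nrf2, nuclear lncRNA and microglia lists reached or crossed 0, and relative to the shift of all genes they kept their sign.

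Markers of other cell types had few measured members. Oligodendrocyte lineage markers had 4 up and 3 down of 8 (median 0.26, adjusted p = 0.253), with Bcas1 up by 5.31 ± 0.14 and Cnp down by 3.69 ± 0.17. Endothelial markers had 3 up and 3 down of 7 (median 0.44, mean -0.46, adjusted p = 0.494), and Flt1 went from 2.30 ± 0.388 CPM to 9.30 ± 1.09 and 4.56 ± 0.407 CPM (SD, n = 2 each). Fibroblast and pericyte markers had 2 up and 4 down of 7 (median -1.14, mean 0.26, adjusted p = 0.634), with Thy1 up by 7.34 ± 0.30 and Cspg4 down by 1.78 ± 0.11. Of the 4 measured microglia markers, 2 rose and 1 fell. Cd68 rose by 1.26 on the log2 scale, Tmem119 fell by 2.68 ± 0.40 from 1.89 ± 0.195 CPM, and Lyz2 did not pass (-0.34). Of the 3 measured ependymal markers, Foxj1 rose by 1.55 ± 0.20. The list of mitochondrially encoded genes had 0 measured members.

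Genes around Miat on chromosome 5 had 5 members up and 3 down of 12 (median 0.16, adjusted p = 0.786). Sez6l, from 112419151 to 112577185, fell by 1.21 ± 0.10, and Adrbk2, from 112910482 to 113015791, by 1.79 ± 0.12. RNA-binding proteins and splicing factors tied to Miat in earlier work had 1 member up and 9 down of 16 (median -0.29, adjusted p = 0.255). Nova1 rose by 1.67 ± 0.11 and Nova2 fell by 1.08 ± 0.12. Abundant nuclear long noncoding RNAs had 5 up and 5 down of 15 (median 0.04, adjusted p = 0.915), with Peg13 up by 3.07 ± 0.18 and Malat1 down by 1.92 ± 0.19.

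Fold changes were not spread evenly over the genome. The 306 genes of chromosome 1 above 100 Mb had a median of -0.76 with both guides (SD 0.09 over the 4 Miat libraries), and 74.2% of them were called lower. Genes of chromosome 1 below 60 Mb had a median of 0.08, with the bin from 0 to 20 Mb at -0.23. The bins from 60 to 80 Mb and from 80 to 100 Mb lay in between, at -0.38 and -0.47. The 420 genes of chromosome 15 had a median of -0.38 (SD 0.04), and 58.8% of them were called lower. The 9170 genes of the other autosomes had a median of 0.07, and 30.6% were called lower. The shifts were -0.71 and -0.83 on chromosome 1 above 100 Mb with sgMiat-6 and sgMiat-96, and -0.43 and -0.38 on chromosome 15. Both regions were singled out after the values were seen. In 10000 random gene sets of the size of chromosome 15, the lower 0.05% of medians began at -0.14. Against random sets of their own sizes, chromosomes 4, 5, 7 and 17 lay above the upper 0.05% of medians, at 0.13, 0.17, 0.19 and 0.17.

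**Figure D3:**
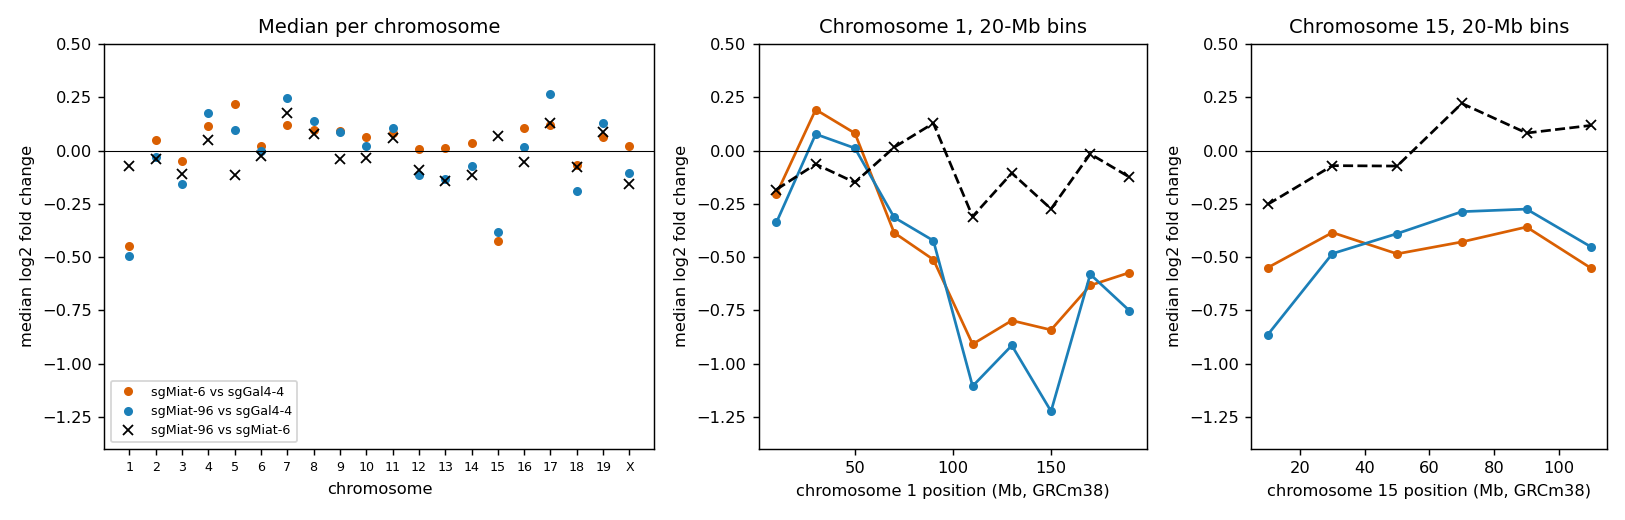
Median log2 fold change per chromosome (left) and in 20-Mb bins along chromosomes 1 and 15 (GRCm38); orange and blue are sgMiat-6 and sgMiat-96 against sgGal4-4, and black crosses are sgMiat-96 against sgMiat-6. Both guides lie at -0.57 or lower in every bin of chromosome 1 above 100 Mb.

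Each guide was also compared with the control on its own, which asks whether different guides aimed at Miat gave like profiles. With sgMiat-6, Gulp1, Mtm1 and Ada were at least 216-fold, 182-fold and 180-fold higher, Pax9 and Gem were at least 130-fold and 104-fold lower, and the kinesin gene Kif1a fell from 293 ± 15.4 to 0.201 ± 0.00411 CPM (SD, n = 2). These genes lay on the same side of the control with sgMiat-96. There Gulp1, Mtm1 and Ada stood at 10.2, 9.59 and 14.45 CPM, and Pax9, Gem and Kif1a at 0.341, 0.0577 and 1.315 CPM. With sgMiat-96, Dcxr and Saysd1 were at least 261-fold and 197-fold higher. The aldehyde dehydrogenase gene Aldh2 rose from 1 count to 81.0 ± 2.27 CPM. Rims3 was at least 166-fold lower, Vcan fell from 336 ± 23.9 to 0.597 ± 0.110 CPM, and Neto1 fell from 7.40 ± 0.563 CPM to 1 count. The genes named for sgMiat-96 also lay on the same side of the control with sgMiat-6. There Dcxr, Saysd1 and Aldh2 stood at 7.195, 13.2 and 59.4 CPM, and Rims3, Vcan and Neto1 at 0.150, 0.979 and 3.31 CPM.

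edgeR called 7007 genes with sgMiat-6, 3558 higher and 3449 lower, and 9011 with sgMiat-96, 4495 higher and 4516 lower. Scaled by total counts alone, the sgMiat-96 calls split into 3535 higher and 5549 lower, with the median of all genes at -0.20. Both guides called 3064 genes higher and 2983 lower, and 44 genes went opposite ways. Independent lists of these sizes would share 1210 and 1178. Fold changes of the guides correlated at 0.92 across genes (0.49 on average in 20 simulations of unchanged groups against the same controls), with a covariance of 2.66 (0.03 simulated), and 84.6% of genes had the same sign (66.5% simulated). Genes are not independent replicates. The simulated values give what sharing these controls produced in unchanged groups. A difference that both control libraries have in common can also add to the excess, by an amount that 2 control libraries could not separate.

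**Figure D4:**
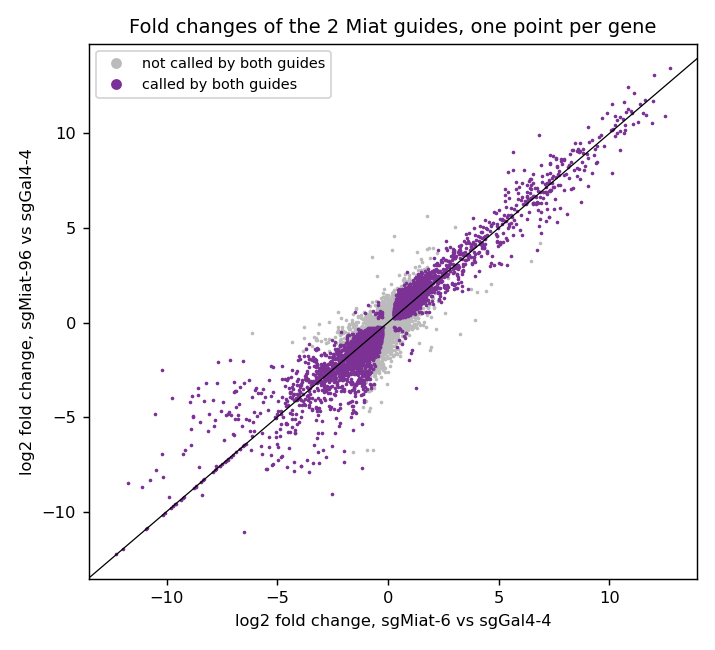
Log2 fold change against sgGal4-4 with sgMiat-6 (horizontal) and sgMiat-96 (vertical), 1 point per gene; purple points were called with both guides and the line marks equal change. The points follow the line, with a correlation of 0.92 across genes.

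The guides were then compared with each other. Ribosomal protein genes were higher with sgMiat-96 in 47 of 49 cases and lower in 0, with a median difference of 0.68, or 0.20 with the length trend removed. Replication-dependent histone genes, a list fixed as a check of quality, were higher in 13 of 28 cases (median 0.89). Glycolysis and hypoxia genes were higher in 15 of 28 (median 0.40) and lysosomal genes in 14 of 30 (median 0.27), while DNA damage repair genes were lower in 12 of 33 (median -0.28). With the length trend removed, the histone list (median 0.28, adjusted p = 0.135), the DNA damage repair list (median -0.13, adjusted p = 0.192) and the oxidative phosphorylation list (median -0.02, adjusted p = 0.419) were not called between the guides, and with an estimated correlation the lowest adjusted p of any list called between them was 0.473. The lymphotoxin receptor gene Ltbr stood at 0.101 ± 0.0732 CPM with sgMiat-6 and 3.79 ± 0.594 CPM with sgMiat-96 (SD, n = 2 each), against 41.7 ± 0.671 CPM in the control. Apoe was higher with sgMiat-96 by 2.34 on the log2 scale (adjusted p = 1.39e-05). The phospholipase gene Plcd1, Pax9 and Runx1 had 0 counts with sgMiat-6 and were at least 18.1-fold, 4.53-fold and 4.53-fold higher with sgMiat-96. With sgMiat-96 they still lay below the control, at 1.36, 0.341 and 0.341 CPM against 7.79, 9.84 and 5.62 CPM.

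On the lower side, Neto1 stood at 3.31 ± 0.715 CPM with sgMiat-6 and had 1 count with sgMiat-96, a fold of 117 lower with a 95% counting interval of 20.6 to 4639. Zbed6 went from 18.2 ± 16.0 to 0.431 ± 0.371 CPM; it lies inside another gene, so its reads can be shared. Rims3 was at least 1.77-fold lower, and Vwa5b1 had 3 counts against 39, a fold of 11.5 lower with an interval of 3.65 to 58.1. In the control Neto1, Zbed6, Rims3 and Vwa5b1 stood at 7.40, 72.25, 14.2 and 5.26 CPM, above the means of both Miat guides. Without sgMiat-96 replicate 1, the calls of Pax9, Runx1, Rims3 and Vwa5b1 were lost (adjusted p = 0.0528, 0.0585, 0.13 and 0.0563). The Rims3 call was also lost without sgMiat-6 replicate 1 and without sgMiat-96 replicate 2 (adjusted p = 0.155 and 0.0875), and with the zeros left as listed (0.14).

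edgeR called 4850 genes between the guides, 2359 higher and 2491 lower with sgMiat-96, and 728 of them differed at least 2-fold. The count fell to 1124 without sgMiat-96 replicate 1 and to 2253 without sgMiat-6 replicate 1. It was 3155 with the trend over transcript length removed. Scaled by total counts alone, the calls split into 1380 higher and 3720 lower, with the median of all genes at -0.14.

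Short transcripts stood higher and long ones lower with the Miat guides. The mean transcript length weighted by counts was 3575 and 3504 bp in the control libraries, 3255 and 3070 bp with sgMiat-6, and 2659 and 2835 bp with sgMiat-96. Over deciles of genes by length, the median log2 fold change with both guides ran from 0.56 at 736 bp to -0.61 at 7621 bp. The Spearman correlation of fold change with length across genes was -0.25 with sgMiat-6, -0.44 with sgMiat-96 and -0.55 between the guides. Ribosomal protein genes were here 81 symbols picked by name, not the fixed list. They took 4.86% and 4.80% of counts in the control libraries, 6.09% and 7.38% with sgMiat-6, and 10.3% and 9.14% with sgMiat-96. The ribosomal RNA precursor Rn45s took 0.467% and 0.379% in the control libraries and between 0.101% and 0.144% in the Miat libraries.

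**Figure D5:**
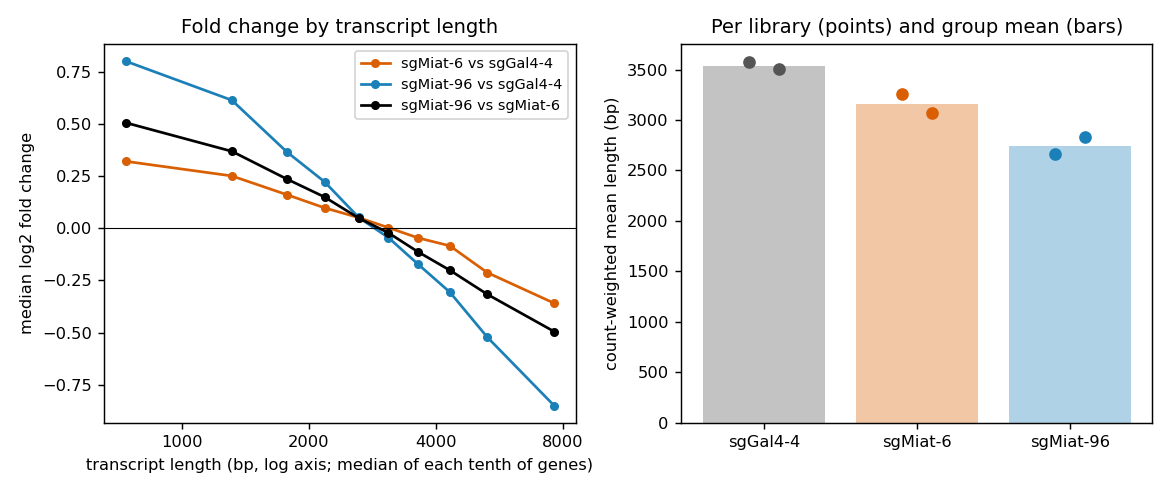
Left, median log2 fold change in deciles of genes by transcript length (log axis, bp); right, mean transcript length weighted by counts in bp, with points for libraries and bars for means of 2 libraries. Fold changes with sgMiat-96 against sgGal4-4 ran from 0.80 at 736 bp to -0.85 at 7621 bp.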

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

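The tests of the length trend against replicates and of the oxidative phosphorylation difference were chosen after the result was seen. The tests of GC content and of the list differences with the length trend removed were set before theirs. Groups of 2 libraries are too small for a test of single outlying samples. What stands out here are differences between the 2 Miat guides, which are aimed at the same transcript.

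edgeR's quasi-likelihood test called 4850 genes between sgMiat-96 and sgMiat-6, and 1124 without sgMiat-96 replicate 1 or 2253 without sgMiat-6 replicate 1. Among named genes, the log2 difference (sgMiat-96 minus sgMiat-6) was 7.71 for Plcd1, 5.73 for Pax9, 5.73 for Runx1 and 5.15 for Ltbr, and -6.57 for Neto1, -5.39 for Zbed6, -4.58 for Rims3 and -3.42 for Vwa5b1. Each of these genes had a lower mean than the control with both guides, so the guides differed in how far it fell. The fitted values of Plcd1, Pax9, Runx1 and Rims3 set a group at 0 counts against a few counts and are no bounds. The calls of Pax9, Runx1, Rims3 and Vwa5b1 were lost without sgMiat-96 replicate 1 (adjusted p between 0.0528 and 0.13). By camera with the preset correlation, 8 lists differed. Ribosomal protein genes (adjusted p = 4.85e-26), oxidative phosphorylation genes (7.6e-06), glycolysis and hypoxia genes (2.09e-05), histone genes (3.92e-05), lysosomal genes (6.59e-05), cholesterol synthesis genes (0.00521) and astrocyte markers (0.0375) were higher with sgMiat-96, and DNA damage repair genes (0.00521) were lower. With an estimated correlation all 8 had an adjusted p of at least 0.473.

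Fold changes between the guides and against the control follow transcript length, and a candidate explanation is that single libraries recovered long transcripts unequally, through RNA integrity or library preparation. It needs the trend among replicates too, and the log ratio of the sgMiat-6 replicates correlated with length at 0.435 across genes, that of the sgMiat-96 replicates at -0.421 and that of the controls at 0.143. For both guides against the control, GC content as the cause is argued against, since with the GC trend removed those fold changes still correlated with length at -0.332. The trend between the guides was not tested with the GC trend removed. By camera with the preset correlation 10 lists differed between guides with the length trend removed, so under that setting length is not the whole of the list differences. An estimated correlation, under which none of the first 8 was called, was not tried with the trend removed, so the question stays open there. Newly called were 5 lists: p53 targets, oligodendrocyte, fibroblast, heat shock and apoptosis. Of the first 8, 5 differed in the same direction: ribosomal protein genes, most of whose difference went with the trend, from a median of 0.68 (SD over members 0.24) to 0.20 (0.22), astrocyte markers, from 0.55 (1.41) to 0.32 (1.31), and the glycolysis, cholesterol and lysosome lists. The other 3 were no longer called: oxidative phosphorylation came level with genes of its length, from a median of 0.41 (0.21) to -0.017 (0.15), histone genes went from 0.89 (0.63) to 0.28 (0.61) and DNA damage repair genes from -0.28 (0.34) to -0.13 (0.28). Whether the share of the trend between control and Miat groups comes from the cells or the libraries stays open. Each group has its own 2 libraries, and no record of how libraries were batched was at hand.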

How the results depend on the processing

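The alternatives added after seeing the data are the zeros as listed, the isoform rows, Rn45s, the length and GC trends, and chromosomes 1 and 15. Over 20 settings that test single genes, 2587 of 2597 values of named genes kept their direction and their side of the threshold, 10 lost the threshold (among them those of Rims3, Pax9, Runx1 and Vwa5b1 between the guides) and 0 reversed. Counts of called genes for both guides, sgMiat-6, sgMiat-96 and between guides stood at 8794, 7007, 9011 and 4850, with 6047 called by both guides in one direction. DESeq2's Wald test gave 8228, 6375, 8435 and 4384, and limma-voom 8817, 7041, 9007 and 4828. With the 2-fold threshold they were 3318, 2582, 4191 and 728, with 2232 for both guides in one direction, fewer by construction. With every transcript row tested they were 13499, 10766, 13818 and 7281, since more rows were tested. Between guides the count was 2473 at an adjusted p under 0.01, by construction, and 3155 with the length trend removed, whose cause was not tested further. With 4 Miat libraries pooled against 2 controls the count for both guides was 5995.

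With 1 library left out, the lone sample of its group was assumed to vary like the others. The counts then ranged from 6986 to 9246 for both guides, 5194 to 7299 for sgMiat-6, 7548 to 9519 for sgMiat-96, 1124 to 5740 between guides and 4493 to 6690 for both guides in one direction. The lowest between guides, 1124, came without sgMiat-96 replicate 1, and 2253 came without sgMiat-6 replicate 1. Miat's adjusted p ranged from 6.92e-15 to 1.44e-05 with sgMiat-6 and from 1.6e-14 to 7.07e-05 with sgMiat-96, and called lists from 10 to 11. With an estimated correlation 0 of 11 lists stayed called, and fry called 30. fry asks whether the members of a list change at all, not whether they change more than other genes. With 66.5% of tested genes called, most lists would pass it, so its calls do not bear on camera's. The estimated correlation was 0.002 for p53 targets, 0 for immediate early genes and -0.002 for Notch genes, below the preset 0.01. A higher correlation among members therefore does not account for the loss of the p53, immediate early and Notch calls. With an estimated correlation camera also takes its p-values from the 3 residual degrees of freedom, which it does not with the preset one. For p53 targets camera's unadjusted p went from 2.34e-07 to 0.0105. The loss of these calls thus goes with the few degrees of freedom. For the other called lists the estimate ran from 0.025 (amino acid response) to 0.868 (ribosomal protein). For these other lists the shares of correlation and of degrees of freedom were not tested further. With the length trend removed 9 lists were called, without chromosomes 1 and 15 also 9, and with the GC trend removed 14. The median of chromosome 1 below 60 Mb was 0.08, and -0.053 scaled by total counts, which moves all genes by -0.126.

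With the replicate number as a block the counts were 8341, 6444, 8562 and 4043, with 5585 for both guides in one direction and 11 lists, and no named gene or list changed its call. Deviations of same-numbered replicates correlated at 0.009, -0.091 and -0.213 across the 3 pairs of groups, which gives no sign of pairing by number. The replicate log ratios follow length in opposite ways, at 0.435 for sgMiat-6 and -0.421 for sgMiat-96. That can hide a shared batch, so pairing is not excluded. Depth limits genes near the floor of 3 counts, such as Rims3 between the guides.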

Other observations

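The tests of chromosome content, label swaps, switched genes and Miat below were all chosen after the results were seen, as were the gene families.

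Families outside the fixed lists were counted by symbol for both guides against sgGal4-4, without pseudogenes, antisense transcripts or copies with the same counts as another member. Glutamate receptor genes, the receptors of excitatory synapses, numbered 6 up and 1 down of 10 (median 1.49, camera adjusted p = 0.0253 over the families, and adjusted p = 0.358 with an estimated correlation). Gria3 and Gria4 came on from 3 or fewer control counts, Grin3a rose by 4.49 ± 0.41 on the log2 scale, and Grm5 fell by 6.01 ± 0.17. Subunits of the V-ATPase, the proton pump of lysosomes, numbered 14 up and 0 down of 19 (median 0.76, adjusted p = 0.00139, and adjusted p = 0.358 with an estimated correlation), with Atp6v0b up by 1.53 ± 0.13 and Atp6v1e1 by 0.95 ± 0.10. With the length trend removed that median was 0.46 (adjusted p = 0.0378). Tubulin genes numbered 9 up and 1 down of 11 (median 0.59, adjusted p = 0.00268, and adjusted p = 0.358 with an estimated correlation), and Tubb3, a neuronal tubulin, rose by 5.26 ± 0.37. Class I and II histocompatibility genes, which share reads among near-identical members, numbered 8 up and 1 down of 10 (median 1.32, adjusted p = 0.0191, and adjusted p = 0.358 with an estimated correlation). That call was lost with the length trend removed (median 0.99, adjusted p = 0.109).

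Proteasome subunits numbered 31 up and 3 down of 36 (median 0.51, adjusted p = 0.00139, and adjusted p = 0.436 with an estimated correlation). Mitochondrial ribosomal protein genes numbered 52 up and 2 down of 77 (median 0.52, adjusted p = 0.000336, and adjusted p = 0.493 with an estimated correlation). Semaphorins, which guide axons, numbered 4 up and 9 down of 16 (median -0.54, adjusted p = 0.037, and adjusted p = 0.358 with an estimated correlation). With the length trend removed these 3 calls were lost, at medians of 0.12, 0.10 and -0.13 (adjusted p = 0.301, 0.352 and 0.239). Hox genes (1 up and 4 down of 9), Fgf genes (0 up and 4 down of 7) and potassium channel genes (13 up and 18 down of 39) were not called as families (adjusted p = 0.104, 0.16 and 0.16).

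Control and Miat libraries differed by shifts over parts of chromosomes and by switched genes, 55 on and 14 silent with both guides, where 26 were silent with sgMiat-6 and 19 with sgMiat-96. The length trend is argued against, since chromosome 1 above 100 Mb stayed at -0.657 with it removed, and so is a single misplaced library, since 0 of the 6 libraries correlated best with a library of another group, which leaves an exchange of whole groups untested. A hypothesis is that the control and Miat libraries came from cell populations that already differed in chromosome content, for example clones. Medians differed by -0.833 between chromosome 1 below 60 Mb and above 100 Mb, by -0.80 and -0.83 with each guide, and by 0.04 between the guides. Bins from 60 to 100 Mb lay in between, at -0.376 and -0.466, so the change was not a single step. The parts compared were chosen from the same medians, so their difference restates the pattern and decides nothing. Whether loss of Miat switched the 68 genes other than Miat cannot be told apart from such a difference either, because no library of the starting cells and only 1 control guide is in the design.

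Miat had 0 counts in 4 of 4 Miat libraries. Too little depth is argued against, since Miat was at least 83.4-fold below the control with the weaker bound of the 2 guides. Repression or disruption by the guides, which the design names, stays open and untested against a hypothesis that the starting cells of the Miat libraries did not transcribe Miat. Miat is 1 of 14 genes silent in those libraries and on in both controls, and the labels name no guide for the others, so the possibilities cannot be told apart without a library of the starting cells.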
